A study of Escherichia coli with 6 samples.

How the data were processed

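RNA sequencing was analysed for 6 samples of Escherichia coli W (ATCC 9637), in 3 groups of 2. The groups were the parental strain, a strain with the S254R change in adenylate cyclase, called AC(S254R) here, and a strain with the T168P change in the cAMP receptor protein, called CRP(T168P) here. Groups and replicate numbers came from the sample labels. Per the labels' protocols, 50 mL cultures in glycerol minimal medium received 2 µM coenzyme B12 and 0.1 mM IPTG at an OD600 between 0.9 and 1.0, and cells were collected 12 h later. Total RNA was depleted of ribosomal RNA and made into stranded libraries, and the labels state that this depletion worked poorly. Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

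The submitters' processing notes name FastQC, Bowtie 1.2.2 and Cufflinks without their roles. The deposited genome and production plasmid files hold, per the file headers and values, the log2 of read depth at each base and strand. For values under 5, the depth recovered from the log2 was a whole number within the rounding of the deposited decimals. The deposited selection plasmid files hold read depth as a linear signal, so they were used without conversion. Positions that were not listed were taken as depth 0. The files carry no normalization between libraries. That the plasmid and genome tracks came from the same reads was not checked. Coordinates are those of the E. coli W sequences named in the files, counted from 1.

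The annotation given for this work belongs to another E. coli strain and build, so gene names were not used here. The fallback fixed before the data were examined was applied, which is windows of 500 nt on each strand, and each result below concerns windows and not genes. The planned tests of gene lists, the level of the adenylate cyclase and cAMP receptor protein genes, and the share of annotated ribosomal RNA were therefore not analysed here. The strand of a window is the strand column of the files, and its relation to the sense strand of transcripts was not checked.

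For each window the mean depth per base was divided by a library factor. This was the median ratio to the geometric mean over chromosome windows with signal in all 6 samples. Windows with a mean scaled depth of at least 2 over the 6 samples were kept, which left 8641 windows. Values were tested as log2(scaled depth + 1) with limma 3.58.1 in R 4.3.3, with a trended prior, all 6 samples and group as the only term. Calls have a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on that log2 scale and understate changes of low windows. The mean depth of each plasmid strand entered the same fit and was adjusted over the 6 plasmid features, and plasmid windows were adjusted separately. Extraction used Python 3.11.15 with numpy 2.4.6.

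Named windows follow a rule fixed before the data were examined and adapted to windows before the fit was run. They are the 12 largest positive and the 12 largest negative log2 fold changes per comparison among called windows in which both samples of one group lay beyond both of the other, with 1 window per run of adjacent called windows. Regions without signal were runs of at least 500 nt with no signal on either strand in both libraries of a group. The requirement that another group cover more than 50% of such a run was set after the data were seen.

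Depth limits precision. The depth summed over genome positions was 1344 and 1413 megabases in the parental libraries, 819 and 675 megabases in the AC(S254R) libraries, and 1031 and 1244 megabases in the CRP(T168P) libraries. A single window took most of it, so the scaling factors, which follow the other windows, were 3.14 and 2.39, 0.571 and 0.524, and 0.578 and 0.966 in the same order. Depth per base is not a number of independent molecules, and no counting interval is given.

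The fit was tested on simulated data with 200 changed windows per mutant and the noise of each group taken from its own replicates, in 10 simulations over 8641 windows. At a log2 change of 4, 43.2% of changed windows were recovered for AC(S254R) against parental, 25.6% for CRP(T168P) against parental and 66.4% for CRP(T168P) against AC(S254R). False calls were 5.85%, 0% and 10.3% of the calls in these comparisons. Fitted to the CRP(T168P) and parental samples alone, the model recovered 80.0% of changes of log2 2 and 100% of changes of log2 4, with 2.36% false calls. Fitted to 2 groups alone, it recovered 0 of 500 changes at each size up to log2 4 for AC(S254R) against parental, and 30 of 500 at log2 4 for CRP(T168P) against AC(S254R).

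Alternatives covered the pseudocount, the filter, the scaling, the value per window, the strands, the samples in the fit, a replicate block, the trended prior and leaving out each sample. Sample weights, the number of depth rises as the window value, and leaving out windows without signal were added after seeing the data.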

Results

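Strand-specific read depth along the genome and 3 introduced plasmids was compared between the parental E. coli W strain that makes 3-hydroxypropionate from glycerol and 2 mutants, AC(S254R) and CRP(T168P). Adenylate cyclase makes cAMP, and the cAMP receptor protein binds it and regulates transcription. Each group had 2 samples. The parental libraries covered 73.9 and 69.9% of chromosome positions per strand, the AC(S254R) libraries 37.4 and 22.6%, and the CRP(T168P) libraries 47.9 and 55.1%. The window from 2926501 to 2927000 on the + strand held 55.7 and 58.7% of the genome signal in the parental libraries, 74.6 and 71.6% in the AC(S254R) libraries, and 76.1 and 75.9% in the CRP(T168P) libraries. Replicates differed least in the parental group, with a standard deviation of the log2 difference over 8641 windows of 0.45, against 0.70 in CRP(T168P) and 1.75 in AC(S254R).

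The comparison of CRP(T168P) with the parental strain asked which parts of the genome changed their signal with the altered receptor. Both CRP(T168P) libraries had no signal on either strand of the chromosome from 2618129 to 2658089, a stretch of 39961 nt, except for 78 nt from 2647271 to 2647348. The parental libraries covered 97.9 and 95.4% of this stretch at mean depths of 41.7 and 32.3, and the AC(S254R) libraries covered 66.3 and 39.8% at mean depths of 14.5 and 12.3. Its 2 runs without signal were 29142 and 10741 nt long, and the next longest in both CRP(T168P) libraries was 2320 nt. Taken instead as adjacent windows under 1% of the library median that the parental libraries covered by more than 50%, the longest run in CRP(T168P) was 15500 nt. Inside the stretch, the window from 2649001 to 2649500 on the + strand had a scaled depth of 170.0 ± 14.5 (SD, n = 2) in the parental strain and was at 0 in both CRP(T168P) libraries.

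**Figure D1:**
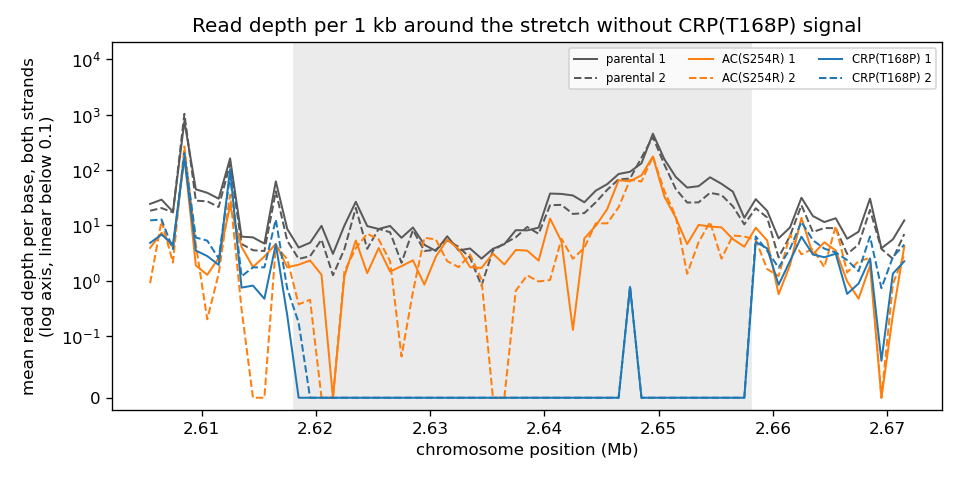
Mean read depth per base in bins of 1 kb (log axis, linear near 0) against chromosome position in Mb, with 1 line per library and the stretch from 2618129 to 2658089 shaded. Inside the shaded stretch the CRP(T168P) lines lie at 0 except in the bin that holds the 78 covered nt and in the edge bins that reach beyond the stretch, on the right in both libraries and on the left in replicate 2, whereas the parental libraries average 41.7 and 32.3.

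Outside this stretch, the window from 3914001 to 3914500 on the − strand fell in CRP(T168P), from a scaled depth of 61.6 ± 1.0 in the parental strain to 0.731 ± 0.332 (SD, n = 2; log2 change −5.19, SE 0.42, limma adjusted p = 0.00624). The window from 2152001 to 2152500 on the − strand fell from 57.2 ± 18.2 to 1.17 ± 0.23 (log2 change −4.72). The window from 1557001 to 1557500 on the − strand fell from 282 ± 106 to 13.3 ± 1.6 (log2 change −4.26). Windows on the + strand starting at 3432001, 4238001, 1337501, 532501 and 1351501 had log2 changes from −3.72 to −2.99. The last 2 of these had changes of 0.067 and 0.58 when positions where the depth rises were counted instead of depth. The windows that rose began at 4280501, 2862001 and 996001, all on the − strand. The first rose from 25.0 ± 8.8 to 1287 ± 177 (log2 change 5.67), the next from 1088 ± 582 to 15326 ± 5452 (log2 change 3.88), and the last from 28.6 ± 7.0 to 174.9 ± 4.0 (log2 change 2.59). In all, limma called 3 windows higher and 33 lower of 8641, and 19 of the 33 lay in the stretch without signal. With this stretch and the windows empty in both AC(S254R) libraries left out, an alternative chosen after seeing the data, limma called 5 of 8553 windows, all lower.

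This count rests on a spread shared with the AC(S254R) libraries. Fitted to the parental and CRP(T168P) samples alone, limma called 210 windows higher and 599 lower, which included all 36 above. When either parental or either CRP(T168P) library was left out, a group held a lone sample. Calls then remained only inside the stretch without signal, so no window described outside it kept its call. With all 6 samples, the 4 calls made without a filter and the 4 made with median depth also lay inside the stretch. Of the 2-group calls, the longest run outside the stretch, chosen after its values were seen, was on the − strand from 892501 to 901000. It held 14 lower windows with a mean log2 change of −2.30. The longest higher runs, chosen the same way, held 6 windows each and lay on the − strand at 2875501 to 2878500, 3526001 to 3529000 and 3599501 to 3602500, with mean log2 changes up to 2.31.

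The comparison of AC(S254R) with the parental strain asked the same of the altered adenylate cyclase. The window from 4280501 to 4281000 on the − strand, also higher in CRP(T168P), rose from a scaled depth of 25.0 ± 8.8 to 1581 ± 1353 (SD, n = 2; log2 change 5.64, SE 0.64, limma adjusted p = 0.0294). The window from 2862001 to 2862500 rose on the − strand from 1088 ± 582 to 32314 ± 8450 (log2 change 4.98), with + strand signal going from 8.02 ± 4.93 to 506 ± 306 (log2 change 5.78). The + strand was small beside the − strand in each library and rose with it. Whether it is a change of its own was not tested. The − strand window from 2886501 to 2887000 rose from 20.9 ± 14.3 to 362 ± 18 (log2 change 4.22, but −0.46 with the median depth per base), and that from 2344001 to 2344500 rose from 0.235 ± 0.290 to 22.0 ± 5.6 (log2 change 4.21). On native plasmid 1, windows on the − strand at 99501 and 75501 rose by log2 values of 3.82 and 3.62. The remaining named higher windows, on the + strand at 3405001, 2857001, 554501 and 3938501 and on the − strand at 4601501, rose by log2 values from 3.51 to 4.03.

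Among windows that fell in AC(S254R), the one from 3637501 to 3638000 on the − strand went from 798 ± 694 to 5.33 ± 4.84 (log2 change −6.89). The one from 3432501 to 3433000 on the + strand went from 106.2 ± 4.6 to 1.62 ± 2.05 (log2 change −5.62). The − strand windows at 3640501, 3862001 and 1679501 fell by log2 values of −5.65, −4.99 and −4.73. On the + strand, the windows at 574001, 1741501 and 1337501 fell by −4.92, −4.77 and −4.32. The windows at 2901001 on the − strand and at 1053501, 4261001 and 212501 on the + strand were at 0 in both AC(S254R) libraries, against scaled depths in the parental libraries of 122.8 and 477 for the first and means of 23.7, 22.6 and 18.2 for the others. Whether the sequence of windows at or near 0 in AC(S254R), here and below, occurs elsewhere in the genome was not settled. Scaled depths at 2901001 were 123 and 477 in the parental and 1352 and 622 in the CRP(T168P) libraries. In the same order, they were 308, 1289, 3254 and 1563 at 3637501, and 113, 511, 1309 and 640 at 3640501. They were 11.4, 33.9, 87.1 and 35.9 at 4261001, and 11.3, 33.8, 87.4 and 36.2 at 4262001, both on the + strand. On the − strand, they were 3.24, 18.4, 32.8 and 16.5 at 4264501, and 3.92, 17.7, 34.7 and 13.4 at 4170501. Windows in these distant places thus varied alike, whereas that at 1053501 did not, and the placement of their reads was not checked. In all, limma called 94 windows higher and 202 lower of 8641.

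These calls depend on a spread that is smaller than that of the AC(S254R) libraries themselves. Fitted to the parental and AC(S254R) samples alone, limma called 0 windows, with 1807 at an unadjusted p under 0.05. This 2-group fit also recovered 0 of 500 simulated changes of log2 4, so its count says little about the calls. The fit to all 6 samples had 2275 such windows. Without parental replicate 1 limma called 1 window, without parental replicate 2 or either CRP(T168P) library 0, and without AC(S254R) replicate 1 or 2 it called 5001 or 3022. The split of higher and lower calls also moved with the scaling, from 31.8% higher to 15.7% with total signal, 0.511% without scaling, and to 241 higher of 602 with quantile normalization. In the AC(S254R) libraries, 64.4 and 71.1% of isolated stretches of 40 to 300 nt with 1 depth throughout had a depth over 1, against 3.92 and 5.04% in the parental and 5.07 and 6.17% in the CRP(T168P) libraries.

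**Figure D2:**
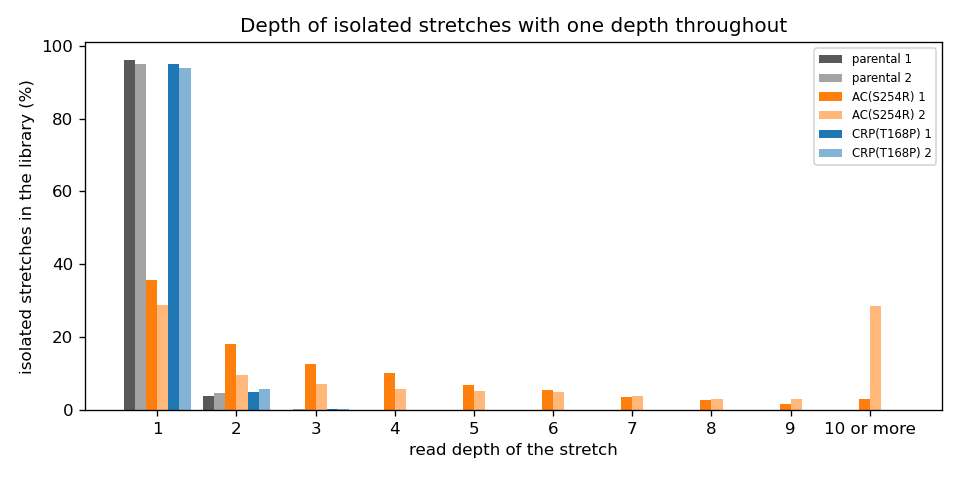
Percentage of isolated stretches in each library (vertical axis) by their read depth (horizontal axis), with 1 bar per library. Depth 1 dominates in the parental and CRP(T168P) libraries, and 64.4 and 71.1% of the stretches exceed it in the AC(S254R) libraries.

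The mutants were then compared with each other. The window from 3637501 to 3638000 on the − strand was higher in CRP(T168P), at 2409 ± 1195 against 5.33 ± 4.84 in AC(S254R) (SD, n = 2; log2 change 8.73, SE 0.83, limma adjusted p = 0.00918). Whether the sequence of this window occurs elsewhere was not settled, as said above. Higher values in CRP(T168P) were also called on the − strand at 3249001, 2878001, 1034501, 4170501 and 3767501 and on the + strand at 4235001 and 4166001, with log2 changes of at least 4.08. The windows at 2901001 and 4264501 on the − strand and at 4262001 and 1053501 on the + strand were at 0 in both AC(S254R) libraries. Their scaled depths in CRP(T168P) were 987 ± 517, 24.7 ± 11.6, 61.8 ± 36.2 and 34.2 ± 17.2. The windows at 3637501, 2901001, 4170501, 4262001 and 4264501 varied alike across libraries, as said above. Whether they are separate changes was not settled.

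Lower in CRP(T168P) than in AC(S254R) were the − strand windows at 3913001, 2152001, 2344001, 4601501 and 4068001. So were the + strand windows at 1786501, 3938501 and 2294501, and the log2 changes of all these ran from −5.50 to −3.90. That of −5.50 was at 3913001 (SE 1.14, limma adjusted p = 0.046). There the AC(S254R) libraries, at 275 and 17.7, lay on either side of the parental ones, at 34.5 and 43.3. On native plasmid 1 the − strand window at 75501 had a log2 change of −4.09. The windows at 2649001 and 2654501 on the + strand and 2647501 on the − strand lie in the stretch without CRP(T168P) signal and had scaled depths of 443 ± 56, 24.2 ± 8.4 and 134.9 ± 26.7 in AC(S254R). In all, limma called 274 windows higher and 186 lower in CRP(T168P), and 55 when only these groups were fitted, a fit that recovered 30 of 500 simulated changes of log2 4. In simulated data, 10.3% of the calls of this comparison were false, above the 5% that the threshold allows. With the windows empty in either mutant as above left out, 283 calls were made. Without either CRP(T168P) library 2 calls were left, and without parental replicate 1 or 2 there were 58 or 56. Without AC(S254R) replicate 1 or 2 there were 5089 or 2963. The share of higher calls was 59.6%, and 80.5% without scaling.

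Across windows, which are not independent replicates, the log2 changes of the mutants against the parental strain had a Pearson correlation of 0.24 and a Spearman correlation of 0.23. Unchanged groups simulated against the same parental libraries gave a median correlation of 0.13 and at most 0.16 in 100 simulations. Without AC(S254R) replicate 1 the correlation was 0.15. This lies under that simulated maximum, which is for all 6 samples and so is not the limit for this smaller set. With 1 library per group the correlation ranged from 0.093 to 0.304. It was 0.14 with a pseudocount of 0.1 and 0.39 without scaling. The simulations were not repeated for any of these alternatives. The covariance was 0.27, against a simulated 0.05. The lists shared 2 higher windows, those on the − strand at 4280501 and 2862001, where independent lists would share 0.033, and 8 lower windows, where independent lists would share 0.771. In 100 simulations of unchanged groups against shared parental libraries, no window was called in the same direction in both comparisons. Lists of the real lengths, taken by smallest p, shared a mean of 0.21 and at most 2 higher windows, and a mean of 1.93 and at most 6 lower windows. With 2 parental libraries the controls were not split, and part of the excess over independent lists may come from sharing them. The simulations shared them too, so their values already include sharing. Whether they hold all of its effect was not tested. Whether the greater depth of the parental libraries adds to the excess was not tested either.

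Of the plasmids, only the selection plasmid had a called strand mean in AC(S254R) against the parental strain. Its + strand rose from a scaled mean depth of 158.6 ± 18.5 in the parental strain to 628.2 ± 9.8 (SD, n = 2; log2 change 1.98, SE 0.32, limma adjusted p = 0.003 over 6 plasmid features). It was 140.2 ± 38.1 in CRP(T168P), lower than in AC(S254R) by a log2 change of −2.18 (adjusted p = 0.00169). All 10 of its + strand windows were called in both of these comparisons. By its mean, the + strand was the weaker strand of this plasmid in each group. Its − strand was at 1299 ± 262, 1990 ± 84 and 1264 ± 65 in the parental, AC(S254R) and CRP(T168P) groups and was not called as a whole, but 5 of its 10 windows were called higher in AC(S254R) than in the parental strain and 3 lower in CRP(T168P) than in AC(S254R). The + strand of production plasmid 2 was at 112884 ± 6056, 61266 ± 25480 and 123924 ± 23083, and that of production plasmid 1 at 8313 ± 361, 7255 ± 5222 and 15257 ± 378, and neither these nor the − strand means were called in any comparison. Single windows were. In AC(S254R) against the parental strain, 3 of 18 were higher on the + strand and 6 higher and 2 lower on the − strand of production plasmid 1, and 1 of 13 was higher on the + strand and 1 higher and 2 lower on the − strand of production plasmid 2. In CRP(T168P) against AC(S254R) these were, in the same order, 3 higher and 2 lower, 1 higher and 3 lower, 1 higher and 3 lower, and 0 higher and 2 lower. No plasmid window was called in CRP(T168P) against the parental strain. The − strand windows at 501, 1001 and 1501 of production plasmid 1 also lay on a weak strand. Their parental scaled depths were 28.5, 19.7 and 24.6, and they rose in AC(S254R) by log2 values of 2.31, 2.07 and 2.35. Rises on strands with the weaker mean were thus not limited to the selection plasmid, and their cause was not tested. In the parental group, the + strand of the selection plasmid was the stronger one in the windows at 1501 and 2001. It was at 259 and 662 there, against 104 and 208 on the − strand, and was the weaker one in the other windows. These + strand windows rose in AC(S254R) by log2 values of 1.99 and 1.92. Without scaling, the selection plasmid log2 change in AC(S254R) was −0.33, so its direction is relative to the chromosome.

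**Figure D3:**
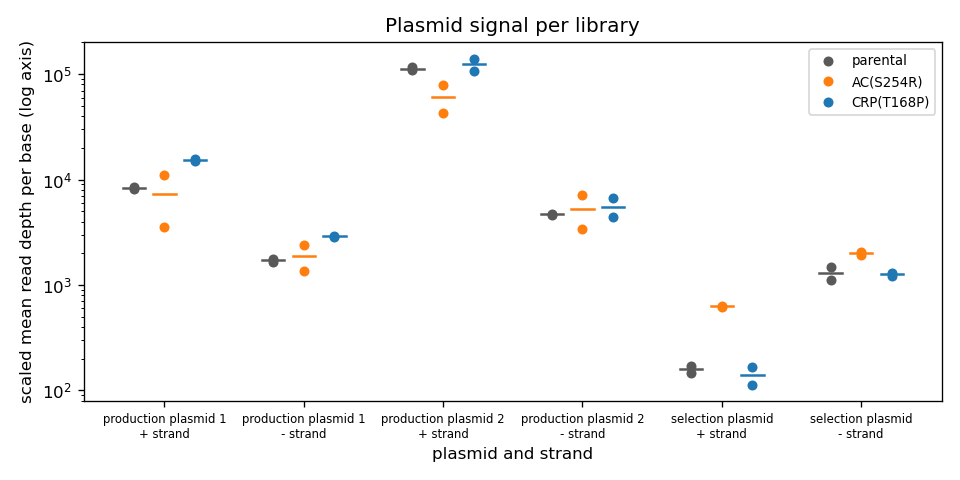
Scaled mean read depth per base of each plasmid strand (log axis), with 1 point per library and a short line at each group mean. The selection plasmid + strand lies at 628.2 in AC(S254R), against 158.6 in the parental strain and 140.2 in CRP(T168P).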

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

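The share of isolated stretches over depth 1 lay above both parental libraries in all 4 mutant libraries, at 64.4 and 71.1% in AC(S254R) and 5.07 and 6.17% in CRP(T168P), against at most 5.04% in the parental strain. Both tests below were chosen after these shares were seen and before their own results were.

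The AC(S254R) values were weighed further. Amplification copies of single fragments would also raise the depth at which other islands of signal begin. Of islands with more than 1 depth, which are not among these stretches, 60.7 and 65.9% began over depth 1 in the AC(S254R) libraries, against 8.67 and 10.4% in the parental and 10.4 and 10.8% in the CRP(T168P) libraries, which is consistent with such copies. Other ways to raise the depth of whole fragments were not tested. RNA species with fixed ends would recur between libraries, but at most 0.221% of the AC(S254R) stretches had the same start and end in the other AC(S254R) library, which argues against them. Both AC(S254R) libraries show the pattern, so any effect of copying on depth is confounded with the AC(S254R) group in each comparison that uses it.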

How the results depend on the processing

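Sample weights, depth rises and leaving out windows without signal were chosen after seeing the data, and the cause of the changes below was not tested unless stated. Counts of called windows follow in the order AC(S254R) against parental, CRP(T168P) against parental, and CRP(T168P) against AC(S254R), where the reported counts were 296, 36 and 460. Without a filter they were 0, 4 and 11, with 3837, 1713 and 3645 at an unadjusted p under 0.05. All of the 4 and 10 of the 11 lay in the stretch without CRP(T168P) signal. With only the groups compared the counts were 0, 809 and 55. Sample weights gave 20, 1244 and 58. Without scaling they were 6853, 4505 and 636, with median log2 changes of −2.21, −1.62 and 0.55 against −0.22, 0.01 and 0.19. Total signal gave 484, 101 and 314, with medians of −0.51, −0.33 and 0.13. Quantile normalization gave 602, 107 and 670. Median depth gave 816, 4 and 961, with higher shares of 13.8, 0 and 83.4%, and the 4 all lay in that stretch. Depth rises gave 968, 22 and 426, with 50.0% higher in the first. A pseudocount of 0.1 gave 112, 33 and 262, and one of 10 gave 288, 9 and 302. A minimum of 20 gave 328, 89 and 318. Summed strands gave 174, 42 and 290. No trend gave 141, 18 and 423. Leaving out windows without signal gave 261, 5 and 283. Leaving out 1 sample gave 0 to 5001, 2 to 823 and 2 to 5089, where a lone sample is assumed to vary like the other groups.

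The replicate numbers share a label only. Replicate differences correlated between groups at 0.00019, −0.19 and −0.12, and the replicate block gave 40, 17 and 104 calls. The correlation of the mutant changes, 0.24 as reported, was 0.14 and 0.31 with pseudocounts of 0.1 and 10, 0.39 without scaling, 0.31 with quantile normalization, 0.33 with depth rises, and 0.15 to 0.31 when 1 sample was left out.

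Called plasmid features, 1, 0 and 1 as reported, were 5, 5 and 4 without scaling and 4, 0 and 3 with median depth, and went up to 3 and 4 in the AC(S254R) comparisons when 1 sample was left out, from 1 each. Without scaling, log2 changes in AC(S254R) against parental reversed to −2.24 and −2.26 on the − strands of production plasmids 1 and 2, and to −0.33 and −1.69 on the + and − strands of the selection plasmid. In CRP(T168P) against parental they reversed to −0.997 (not called, adjusted p = 0.0592) and −1.12 on the + and − strands of production plasmid 1 and to −1.75 and −1.67 on production plasmid 2. With median depth the + strand of production plasmid 2 reversed to 1.34 in AC(S254R) against parental and −1.54 in CRP(T168P) against AC(S254R). Plasmid changes called under neither setting also reversed. In AC(S254R) against parental, the − strands of production plasmids 1 and 2 went to −0.24 and −0.26 with total signal, and the latter to −0.11 with median depth. In CRP(T168P) against parental, the + and − strands of production plasmid 2 went to −0.28 and −0.20 with total signal and to −0.20 and −0.10 with median depth, and those of the selection plasmid to 0.087 and 0.23 with median depth. In CRP(T168P) against AC(S254R), the − strand of production plasmid 1 went to −0.73 with median depth. Leaving out 1 sample gave changes on both sides of 0, from −1.34 to 0.35, −0.43 to 0.43 and −0.59 to 0.55 on the + and − strands of production plasmid 1 and the − strand of production plasmid 2 in AC(S254R) against parental, from −0.076 to 0.32 and −0.084 to 0.49 on production plasmid 2 and −0.47 to 0.073 and −0.23 to 0.18 on the selection plasmid (+, then − strand) in CRP(T168P) against parental, and from −0.36 to 0.75 on the − strand of production plasmid 2 in CRP(T168P) against AC(S254R). Of the named windows, the one at 2886501 reversed to −0.46 with median depth, and those at 532501 and 1351501 in CRP(T168P) against parental reversed to 0.067 and 0.58 with depth rises.

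Runs without signal that the parental strain covered summed to 400296 nt in AC(S254R) and 100118 nt in CRP(T168P), to 889012 and 200693 nt with a minimum run of 200 nt, and to 139500 and 64000 nt for windows under 1% of the library median, whose longest runs were 3000 and 15500 nt, against 4481 and 29142 nt for runs without signal. Count models and gene lists were not run, since depth per base is not a count and no gene names were used, and the ribosomal RNA share was not computed.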

Other observations

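Of windows with a parental mean depth of at least 20, a limit set after seeing the data, 19 outside the CRP(T168P) stretch had no signal in either AC(S254R) library. Most lay in a few places that kept signal in the other groups. The window from 2901001 to 2901500 had mean depths of 385 and 1142 in the parental and 782 and 601 in the CRP(T168P) libraries. The run from 4262001 to 4265000 had 25.8 and 81.0 in the parental and 43.4 and 33.6 in the CRP(T168P) libraries, and that from 4474001 to 4476500 had 9.80 and 38.7, and 16.9 and 12.9.

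All tests of the stretch without CRP(T168P) signal were chosen after it was seen. Too little depth is argued against, because windows elsewhere with matched parental depth lacked CRP(T168P) signal in 0.347% of cases. Lower transcription that keeps the background seen elsewhere was not decided. Inside, 33 windows had a parental mean depth of at least 20, and 32 of them had no signal in either CRP(T168P) library. This follows from choosing the stretch as 2 empty runs. Outside, 0 of 4040 such windows had none. Of these, 35 windows in 22 separate places were at least 8-fold lower in CRP(T168P), at most 84.9-fold. That 0 of the 22 places had none in both libraries (upper 95% limit 15.4%) follows from the 0 of 4040. Of the 35 windows, 1 had none in 1 library. Their median parental depth was 88.5, against 48.4 for the 33 inside, so signal could remain there more easily. Lowered places elsewhere thus kept some signal, but a stronger fall inside the stretch stays open. Such a fall, silencing that removes the background as well and a segment missing from the DNA of this strain cannot be told apart here. The 99.8% of positions inside that lacked signal in both libraries follows from the same choice, so it decides none of these, and DNA was not measured. A difference in how the CRP(T168P) reads were processed before deposit stays open and untested.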
